A study of Vitis vinifera with 26 samples.

How the data were processed

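RNA from berry tissue was sequenced on an Illumina instrument, per the labels' protocols. The 26 libraries fell into 6 groups, control and 1-MCP-treated clusters at 6, 7 and 8 WAA, with groups taken from the source names and replicate numbers from the sample titles. The description label calls all 26 libraries, controls included, treated clusters, so which libraries are controls, and every direction of a 1-MCP effect, rests on the source names and titles. A plant is a biological replicate per the series design text, and the same text says that the treated and the control cluster came from the same plant.

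The authors deposited 1 table per library with a value for each of 90542 assembled isoforms, and a table of isoform attributes with locus, reference identifier, coordinates and length. The deposited values are a signal on a scale set by the authors and they are not read counts. Bowtie2 2.2.3 is named in the submitters' processing notes, and the file headers have the form of Cufflinks tables. The program that made the values, the genome build and the annotation are not given in the sources used here, so coordinates are printed as the files give them. The other measure in the attribute table is isoform length in bases, as deposited.

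Within each library almost all values were multiples of 1 constant step, which was 1.027 in 18 libraries and at most 1.055. Division by this step gave the units used here. Between 97.7% and 98.5% of locus sums were within 0.01 of a whole number of units, against 80.5% to 90.3% of isoform values, so isoform values were summed per assembled locus. The step did not depend on length, so values are not per kilobase. Between 74.1% and 77.2% of isoforms were listed at 0, the highest locus reached 23 units, and 11402 of 33229 loci were listed at 0 in all libraries. A value of 0 is therefore written as listed at 0. The variance of a locus within a group was on average 0.303 to 0.348 times its mean, too even for sampled reads, so units were not treated as reads and no count test was run. The number of sequenced reads is unknown. Detection rose with length, from 4.35% of locus values for loci of up to 500 bases to 75.1% for loci of 2000 to 5000 bases. Correlations between libraries on the log2 scale ranged from 0.716 to 0.825, so no library was a copy of another.

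The groups, tests, gene lists, rule for named loci and most alternatives were fixed before the data were examined, for counts or FPKM. The values were neither, and the branch for normalised values was used. Loci with a value of at least 1 in at least 3 libraries of the fit were kept, values were transformed as log2(value + 1), and limma 3.58.1 in R 4.3.3 was fitted with empirical Bayes moderation without trend or robust options. Fold changes are on the log2(value + 1) scale and understate changes of low loci. P-values were adjusted by the Benjamini-Hochberg method over all tested loci with a threshold of 0.05. The 1-MCP effects were estimated in all 26 libraries with a block for each of 13 plants and 1 treatment coefficient per week. Development was tested in the 13 control libraries with a mean per week. Same-numbered treated and control libraries deviated from their group means with correlations between -0.089 and 0.092, all above 0 except at replicate 4 of 7 WAA. Libraries of other numbers in the same week had a median of -0.013 and a range of -0.105 to 0.108. The values thus lean only weakly towards the pairing, which rests on the series design text.

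In data resampled from the real loci with 200 loci raised, the 1-MCP comparison at 7 WAA recovered 20.5% of changes of 1 unit, 49.5% of 2 units and 69.0% of 3 units over 18118 to 18125 loci. With the 3 plants of 6 WAA it recovered 16%, 32% and 43%. The comparison of 7 and 8 WAA recovered 25.5%, 59.5% and 79.0% over 17101 to 17114 loci. In 20 resampled data sets without change, limma called at most 7 loci at 6 WAA, 1 at 7 WAA and 3 at 8 WAA for 1-MCP. For development it called at most 18, 7 and 17 from 6 to 7, 7 to 8 and 6 to 8 WAA. Each locus was drawn on its own over all 26 libraries, so library effects, plant pairing and correlation between loci were lost. These counts may therefore understate the calls that chance makes in the real data, where splits of the labels gave more in several comparisons. The recovery rates carry the same limit.

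Gene names were not printed. The files do not pair reference identifiers with names, and 0 of the identifiers matched the RefSeq gene table of assembly GCF_030704535.1. Of the 31 lists of genes, 8 held identifiers recalled from the grapevine literature and were usable after adding the prefix used in the files. The stilbene synthase list held only the beginnings of identifiers, and every locus with such an identifier was taken, which gave 76 loci. It may therefore hold other genes of the same regions. The membership of the lists could not be checked against the files. The other lists, ethylene biosynthesis and signalling among them, rested on descriptions and were not analysed here. Lists with at least 3 tested loci were tested with camera (preset correlation 0.01, and an estimated one) and fry, adjusted over the lists within a comparison. The fry test asks whether the members of a list move in one direction on balance.

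The rule for named loci took, among loci past the threshold, the 8 largest changes in each direction with the same direction in all plants or with groups that did not overlap, a mean at or above the median of the tested loci and a reference identifier. It added up to 2 members of each list past the threshold over all loci. Its part on ethylene genes was not applied, since those lists were not analysed here. Where no locus passed, those with the smallest p were named. At most 2 identifiers that rose and 2 that fell are printed per comparison. Loci spanning several identifiers, and lists of near-identical copies, may mix neighbouring genes in their values.

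Totals, list totals and slopes of the 1-MCP effect on the developmental change were compared over plants with exact two-sided sign-flip permutation tests in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Alternatives fixed beforehand were the fit without the plant block, a fit per week, quantile normalization, no filter, a filter at 5, a pseudocount of 0.1, a log2 fold change of at least 1, and leaving out each plant or control library. Isoform-level values, sums per reference identifier, trend and robust moderation, and values rounded to whole units were added after the data were examined. The whole units were fitted over all loci, without the loci that held 1 value in all libraries of the fit, and over the loci that differed from their median value in at least 5 libraries. The last filter removes loci that change only in the 3 libraries of a 6 WAA group, so it does not test them.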

Results

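Berry clusters of the grapevine cultivar 'Pinot Noir' (Vitis vinifera) were profiled by RNA sequencing at 6, 7 and 8 weeks after anthesis (WAA), around the onset of ripening. Clusters on 8-year-old plants were exposed inside a bag to 5 ppm 1-methylcyclopropene (1-MCP), a gas that blocks ethylene receptors, for 24 h. Mock-treated clusters, for which the labels give no further detail, were the controls, and sampling followed after 24 h. A treated and a control cluster were taken from each plant. The 26 libraries came from 3 plants at 6 WAA, 5 at 7 WAA and 5 at 8 WAA. Each combination of week and replicate number was counted as 1 plant, which gives 13. The labels do not say whether plants were shared between weeks, so these 13 may not be separate plants. Each library held between 20368 and 23485 units over 33229 assembled loci, where a unit is the constant step of that library's deposited values, and between 13912 and 15261 loci were detected at 0.5 units or more. Between 63.7% and 69.6% of the detected loci stood at exactly 1 unit, so the values show mainly whether a locus was present in a library, and they resolve gradual changes poorly.

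Treated clusters held more units than the control cluster of the same plant in 12 of 13 plants. The mean difference was 759.9 ± 777.0 units (SD, n = 13), or 3.51% of the control mean (exact two-sided sign-flip permutation test, p = 0.00342, adjusted p = 0.00879 over 3 measures). The difference was 494.0 ± 584.7 units at 6 WAA (n = 3), 828.6 ± 655.4 at 7 WAA (n = 5) and 850.8 ± 1068.4 at 8 WAA (n = 5). The number of detected loci was higher in 8 of 13 treated clusters and did not pass the same exact test (mean difference 159.5 ± 454.4 loci, p = 0.229). Units per detected locus were higher in 11 of 13 treated clusters, by 0.0356 ± 0.0391 on average (exact test, p = 0.00586, adjusted p = 0.00879). These 3 measures were compared after the data had been examined.

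**Figure D1:**
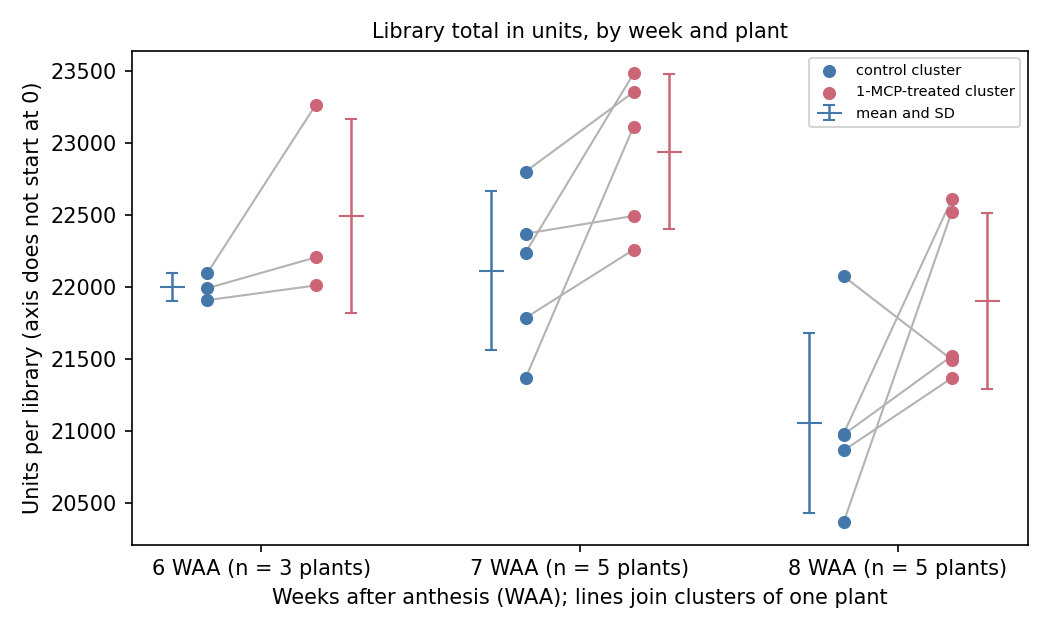
Library totals in units (vertical axis, which does not start at 0) for control and 1-MCP-treated clusters at 6, 7 and 8 WAA, with libraries as points, grey lines joining the clusters of 1 plant, and bars for the mean and SD. The treated library lay above its control in 12 of 13 plants.

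The comparison at 6 WAA asked which loci responded to 24 h of 1-MCP 6 weeks after anthesis. Of 18622 tested loci, 8 passed the threshold, with 5 higher and 3 lower in treated clusters. VIT_206s0061g01370 (locus XLOC_025075, chromosome 6, 19195827 to 19197314) was listed at 1, 0 and 1 units in control replicates 1 to 3 and at 2, 1 and 2 units in the treated clusters of the same plants, a log2 fold change of 0.73 ± 0.07 (SE, limma, adjusted p = 0.00119). It rose by 1 unit in each plant and stood at 1 unit in all libraries of 7 and 8 WAA, which share the fit. Its SE and p therefore do not measure a spread between plants either. VIT_214s0030g00575 (XLOC_008712, chromosome 14, 4400207 to 4705450) fell from 2 units in all 3 controls to 1 unit in all 3 treated clusters, with a log2 fold change of -0.59 ± 0.03 (SE, limma, adjusted p = 1.08e-06). Its units did not vary within any group (SD 0), so this SE and p do not measure a spread between plants. They reflect the differing steps of the libraries and the moderation. VIT_204s0023g02590 (XLOC_020875, chromosome 4, 19138402 to 19142192), which lies outside the rule for named loci and was named at this week after its values were seen, was listed at 0 in all 3 controls and at 2, 2 and 1 units in the treated clusters (limma, adjusted p = 0.00809). Of the 8 loci, 3 were detected in every treated library and in no control, 2 showed the opposite, and 2 carried no reference identifier. At 3 of the 8 the residual SD was under 0.05 on the log2 scale. No list of genes fixed beforehand passed a test at this week. Without the block for plants 19 loci passed, with only the 6 WAA libraries in the fit 140 passed, and 21, 15 and 18 passed without replicate 1, 2 or 3, while VIT_206s0061g01370 did not pass in the first 2 of these fits (limma, adjusted p = 0.136 and 0.810) or with a pseudocount of 0.1 (0.315). The call of VIT_204s0023g02590 was lost with only the 6 WAA libraries (limma, adjusted p = 0.678) and without replicate 1 (0.0548) or 2 (0.0744). When values were rounded to whole units, 8 loci passed. When the loci with 1 whole-unit value in all libraries were then left out, 6 passed, but VIT_206s0061g01370 (limma, adjusted p = 0.125) and VIT_214s0030g00575 (0.236) did not. Data resampled without any change, with each locus drawn on its own, gave up to 7 calls.

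The comparison at 7 WAA asked the same question a week later, and the stilbene synthase list had more units in treated clusters. Stilbene synthases make resveratrol and related defence compounds from phenylpropanoid precursors. The list took every locus whose identifier begins as recalled for the stilbene synthase regions of chromosomes 16 and 10. Its 76 loci may thus include other genes of these regions beside near-identical copies. The list total was 28 ± 14.7 units in controls and 48.6 ± 15.96 units in treated clusters (SD, n = 5), and it was higher in treated clusters of 5 of 5 plants. The mean difference of 20.6 ± 14.9 units had an exact sign-flip p of 0.0625, the smallest that 5 plants can give, and an adjusted p of 0.1875 over 3 weeks. Of 53 tested members, 40 were higher by over 0.05 on the log2 scale and 7 were lower. None passed the threshold over all loci or adjusted over the list alone. The camera test with a preset correlation of 0.01 gave an adjusted p of 1.39e-08, the test with an estimated correlation gave an adjusted p = 0.0876, and fry gave an adjusted p = 0.0810.

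Of the 18622 loci tested at 7 WAA, 1 passed the threshold. This locus (XLOC_011243, chromosome 16, 13708239 to 13712106), which carries no reference identifier and lies outside the rule for named loci, was named after its values were seen. It was listed at 2, 2, 2, 1 and 2 units in the controls and at 1, 1, 1, 0 and 1 units in the treated clusters of the same plants (limma, adjusted p = 0.0305). It fell by 1 unit in each plant and was listed at 0 in all libraries of 8 WAA, which share the fit. The p of this locus therefore does not measure a spread between plants of 7 WAA. Its call was lost without replicate 1, 2, 3 or 12 (limma, adjusted p between 0.0520 and 0.155), without the block for plants (0.583), with only the 7 WAA libraries (0.631), with a pseudocount of 0.1 (0.610) and when the loci with 1 whole-unit value in all libraries were left out (0.352), and the count was 2 without replicate 2 and 0 without replicate 3 or 12.

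**Figure D2:**
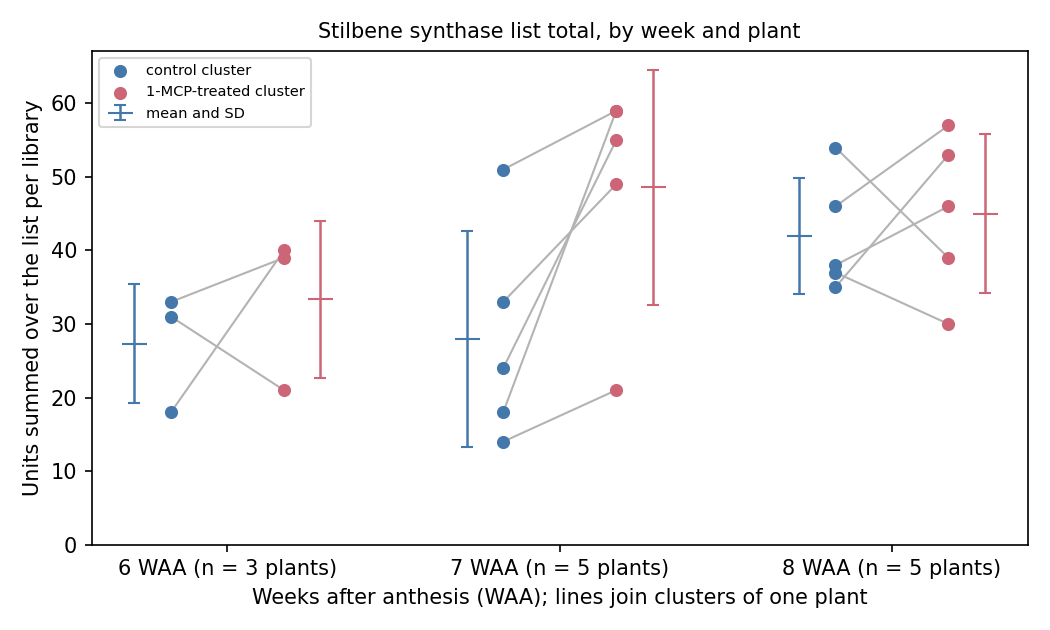
Units summed over the 76 loci of the stilbene synthase list in each library (vertical axis) at 6, 7 and 8 WAA, with libraries as points, grey lines joining the clusters of 1 plant, and bars for the mean and SD. At 7 WAA the treated cluster lay above its control in 5 of 5 plants, at 8 WAA in 3 of 5 and at 6 WAA in 2 of 3.

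At 8 WAA, 0 of 18622 loci passed the threshold in limma, and 841 had an unadjusted p under 0.05. That count is below a share of 0.05 of the tested loci, the share expected without any effect. The loci with the smallest p, which did not pass, are given as values. VIT_208s0007g01470 (chromosome 8, 15575804 to 15577007) was listed at 1 unit in 5 of 5 controls and at 0 in 5 of 5 treated clusters (limma, adjusted p = 0.109). VIT_204s0023g02590, higher in treated clusters at 6 WAA, was here present in 5 of 5 controls and 1 of 5 treated clusters (limma, adjusted p = 0.11). VIT_207s0104g00960 (chromosome 7, 2082660 to 2083736) was listed at 0 in 5 of 5 controls and at 1 unit in 4 of 5 treated clusters (limma, adjusted p = 0.129). A locus that spans 4 reference identifiers (XLOC_015978, 3944610 to 4319279 on an unplaced scaffold assigned to chromosome 18) had 4, 1, 0, 0 and 0 units in controls and 8, 4, 2, 2 and 2 in the treated clusters of the same plants (limma, adjusted p = 0.11). Each of the 4 passed in some other fit (limma), VIT_207s0104g00960 without the block for plants (adjusted p = 0.0145), VIT_208s0007g01470 with only the 8 WAA libraries (0.000269), that locus and VIT_204s0023g02590 with a pseudocount of 0.1 (0.0392 for both), and XLOC_015978 with a filter at 5 (0.00907). Leaving out replicate 3, 4 or 5 gave 3, 2 or 1 calls, and 5 loci passed without the block for plants.

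The flavonoid backbone list, enzymes that supply anthocyanins, tannins and flavonols, had 17.8 ± 2.4 units in controls and 15.4 ± 0.9 in treated clusters at 8 WAA (SD, n = 5). Of its 15 tested members, 1 was higher and 5 were lower by over 0.05 on the log2 scale, and none passed over all loci or adjusted over the list alone. Only fry placed the list past the threshold (adjusted p = 0.0178), against an adjusted p of 0.172 with camera and an adjusted p = 0.423 with an estimated correlation. This call was lost without the block for plants (fry adjusted p = 0.0578) and without replicate 1, 3 or 4 (fry adjusted p between 0.0593 and 0.0615). Control replicate 3 stood at 22 units, and without that plant the treated-minus-control difference in list total was -1.53 units. The stilbene synthase list had 42.0 ± 7.9 units in controls and 45.0 ± 10.8 in treated clusters at 8 WAA, and 27.3 ± 8.1 against 33.3 ± 10.7 at 6 WAA. The exact sign-flip p was 0.625 at 8 WAA (n = 5) and 0.75 at 6 WAA (n = 3).

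Averaged over the 3 weeks, 7 loci passed the threshold, 4 higher and 3 lower in treated clusters, and 0 when the loci with 1 whole-unit value in all libraries were left out (limma, 1113 at an unadjusted p under 0.05). None of them moved the same way in all 13 plants, and most of them had also passed at 6 WAA. They included VIT_214s0030g00575 (limma, adjusted p = 5.41e-05) and VIT_206s0061g01370 (0.0449), and the latter was lost without the block (0.732), without the filter (0.0519), with a pseudocount of 0.1 (0.808) and without any plant of 7 or 8 WAA (0.0717 to 0.131). The stilbene synthase list was higher in camera (adjusted p = 0.000172), but not with an estimated correlation (adjusted p = 0.396) or without replicate 1 of 6 WAA (camera adjusted p = 0.0644). The count was 18 without replicate 1 and 12 without replicate 2 of 6 WAA, 4 without replicate 12 of 7 WAA and 11 without replicate 3 of 8 WAA. The effect of 1-MCP differed between 6 and 7 WAA at 7 loci and between 6 and 8 WAA at the same 7 loci. All of these were among the 8 loci called at 6 WAA, so these sets are not separate results. VIT_214s0030g00575 and VIT_206s0061g01370 were among both sets, since each stood at 1 unit in all libraries of both groups at 7 and 8 WAA. The calls of VIT_206s0061g01370 were lost without the block for plants (limma, adjusted p = 0.559 and 0.695), with only the weeks compared (0.204 and 0.114) and with a pseudocount of 0.1 (0.829 and 0.906). VIT_204s0023g02590, again named after its values were seen, was in both sets (limma, adjusted p = 0.00986 and 0.000939), and between 6 and 7 WAA it did not pass with only the weeks compared (0.183). When the loci with 1 whole-unit value in all libraries were left out, 0 loci passed between 6 and 7 WAA (limma, 931 at an unadjusted p under 0.05) and 1 between 6 and 8 WAA, and of these 3 identifiers VIT_204s0023g02590 passed between 6 and 8 WAA (limma, adjusted p = 0.00401). Without replicate 1, 2 or 3 of 6 WAA these counts were 22, 15 and 16 between 6 and 7 WAA and 23, 12 and 14 between 6 and 8 WAA. They were 13 without replicate 1 of 7 WAA and 12 without replicate 3 of 8 WAA. No locus differed between 7 and 8 WAA in limma. With 899 loci at an unadjusted p under 0.05, the count was again below a share of 0.05 of the tested loci. In limma, 1 to 3 loci differed without replicate 1, 2 or 4 of 7 WAA or replicate 3, 4 or 5 of 8 WAA. Among the smallest p there, VIT_207s0005g04650 (chromosome 7, 7863914 to 7888972) had 2.2 ± 0.45 units in controls and 1.6 ± 0.89 in treated clusters at 7 WAA, against 1.2 ± 0.45 and 2.8 ± 0.84 at 8 WAA (SD, n = 5, limma, adjusted p = 0.312). The camera test placed the effect on the stilbene synthase list higher at 7 than at 6 WAA (adjusted p = 0.0330) and lower at 8 than at 7 WAA (adjusted p = 0.000189). With an estimated correlation the adjusted p was 0.978 and 0.403, and the first call was lost without replicate 2 or 3 of 6 WAA or 1 or 4 of 7 WAA (camera adjusted p between 0.121 and 0.916). Exact permutations of the plants' differences in list total between weeks gave p = 0.232 (3 and 5 plants) and p = 0.127 (5 and 5 plants).

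Development was compared among the 13 control clusters only, over 17172 loci. Between 7 and 8 WAA, 102 loci passed the threshold, of which 94 were lower and 8 were higher at 8 WAA. Of these, 77 were detected in 5 of 5 controls at 7 WAA and in 0 of 5 at 8 WAA, and 6 showed the opposite. At 26 of the 102 the residual SD was under 0.05 on the log2 scale. A locus spanning 3 reference identifiers (XLOC_017693, chromosome 2, 2029174 to 2040913) was listed at 9, 2, 4, 7 and 1 units at 7 WAA and at 0 in all 5 controls at 8 WAA (limma, adjusted p = 0.0415). The locus XLOC_015978, described above, fell from 8.40 ± 1.14 units (SD, n = 5) to values of 4, 1, 0, 0 and 0 (limma, adjusted p = 0.0196). VIT_205s0020g03880 (chromosome 5, 5537278 to 5545365) rose from 1 unit in all 5 controls to 2.40 ± 0.55 units, a log2 fold change of 0.76 ± 0.13 (SE, limma, adjusted p = 0.0213). The count stayed between 91 and 146 whichever control library was left out. The call of XLOC_017693 was lost without replicate 1, 3 or 4 of 7 WAA or any control of 8 WAA, that of XLOC_015978 without replicate 1 or 4 of 7 WAA or 3, 4 or 5 of 8 WAA, and that of VIT_205s0020g03880 without replicate 1, 3 or 4 of 7 WAA or 3 or 4 of 8 WAA (limma, adjusted p between 0.0540 and 0.109). In a fit of all 26 libraries XLOC_017693 (limma, adjusted p = 0.0865) and VIT_205s0020g03880 (0.0514) did not pass. With a pseudocount of 0.1 XLOC_015978 did not (0.0716), and with whole units XLOC_017693 did not (0.0507).

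Among the lists, 1 flavonoid locus rose between 7 and 8 WAA in controls. This locus of the flavonoid backbone list (XLOC_015117, chromosome 18, 10907075 to 10933427) spans 2 reference identifiers and was listed at 0 in 5 of 5 controls at 7 WAA and at 1, 1, 2, 1 and 2 units at 8 WAA (limma, adjusted p = 0.0165). It was already listed at 1, 0 and 1 units in controls at 6 WAA. In treated clusters at 8 WAA it was listed at 0, 1, 1, 0 and 0 units. It was 1 of 15 tested members past the threshold, over all loci and adjusted over the list alone. The stilbene synthase list was higher at 8 than at 7 WAA in camera (adjusted p = 1.35e-05), with an adjusted p = 0.234 with an estimated correlation. Of its 43 tested members, 28 were higher and 6 lower by over 0.05 on the log2 scale, 0 passed over all loci and 1 passed adjusted over the list alone. The proanthocyanidin list, enzymes and regulators of condensed tannin synthesis, had 4.80 ± 0.45 units at 7 WAA and 3.40 ± 0.55 at 8 WAA (SD, n = 5). It passed in fry (adjusted p = 0.0332) but not in camera (adjusted p = 0.147; adjusted p = 0.377 with an estimated correlation) and not without replicate 1, 3 or 12 of 7 WAA or 4 or 5 of 8 WAA (fry adjusted p between 0.0729 and 0.108), and 1 of its 4 tested members passed adjusted over the list alone.

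Between 6 and 8 WAA, 205 loci passed the threshold in controls, 170 lower and 35 higher at 8 WAA. Of these, 143 were detected in all controls at 6 WAA and in 0 controls at 8 WAA, and 31 showed the opposite. At 38 of the 205 the residual SD was under 0.05 on the log2 scale. VIT_204s0044g00700 (chromosome 4, 21749923 to 21754454) was listed at 0 in 3 of 3 controls at 6 WAA and at 2, 3, 1, 2 and 2 units at 8 WAA (limma, adjusted p = 0.00481). A locus spanning 2 reference identifiers (XLOC_031839, 9116201 to 9171712 on unplaced sequence) was listed at 0 in 3 of 3 controls at 6 WAA and at 3, 2, 3, 3 and 3 units at 8 WAA (limma, adjusted p = 0.0152). XLOC_017693 and XLOC_015978 were lower at 8 WAA here too (limma, adjusted p = 0.0265 and 0.0446). The stilbene synthase list was again higher at 8 WAA in camera (adjusted p = 0.000864), with an adjusted p = 0.587 with an estimated correlation and a camera adjusted p of 0.0609 without replicate 1 of 6 WAA. In it 1 of 43 tested members passed over all loci (XLOC_011954, chromosome 16, 16618990 to 16624707, listed at 0 in 3 of 3 controls at 6 WAA and at 2 units in 5 of 5 at 8 WAA, limma, adjusted p = 0.0472) and 2 passed adjusted over the list alone. The calls of these loci were lost without single controls (limma, adjusted p between 0.0549 and 0.171), XLOC_031839 without any of 6 WAA, XLOC_017693 without any but replicate 2 of 6 WAA, XLOC_015978 without any but replicate 1 of 8 WAA and XLOC_011954 without any, while that of VIT_204s0044g00700 held whichever control was left out. In a fit of all 26 libraries XLOC_031839 did not pass (limma, adjusted p = 0.0545). XLOC_015978 and XLOC_011954 did not pass with a pseudocount of 0.1 (0.122 and 0.0714) or without the filter (0.0516 and 0.0544), and XLOC_011954 did not with whole units (0.0547) or with trend and robust moderation (0.0506). The count of 205 was 141 without control replicate 1 of 6 WAA and between 96 and 116 without any other of the 8 control libraries.

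Between 6 and 7 WAA, 29 loci passed the threshold in controls, 10 higher and 19 lower at 7 WAA. VIT_204s0008g03920 (chromosome 4, 3246966 to 3250642) was listed at 0 in 3 of 3 controls at 6 WAA and at 1, 4, 2, 2 and 3 units at 7 WAA, and VIT_204s0044g00700 was listed at 0 and then at 1, 2, 2, 2 and 1 units (limma, adjusted p = 0.0389 for both). VIT_214s0030g00575 and VIT_203s0063g02050 (chromosome 3, 5319855 to 5322663) both fell from 2 units in all 3 controls to 1 unit in all 5, a log2 fold change of -0.58 ± 0.02 (SE, limma, adjusted p = 8.29e-09). Their units did not vary within any control group, so this SE and p do not measure a spread between plants. VIT_214s0030g00575 stood at 2 units only in the 3 controls of 6 WAA, which also gave its 1-MCP call. Several other loci called for 1-MCP at 6 WAA, VIT_204s0023g02590 among them, also passed between 6 and 7 WAA in the same direction. Both comparisons use the controls of 6 WAA, so these calls are not independent. Of the 29 loci, 12 had a residual SD under 0.05 on the log2 scale. When the loci with 1 whole-unit value in all libraries were left out, 27 loci passed, without VIT_214s0030g00575 and VIT_203s0063g02050 (limma, adjusted p = 0.139 for both). The call of VIT_204s0008g03920 was lost without any control of 6 WAA or replicate 3, 4 or 12 of 7 WAA, and that of VIT_204s0044g00700 without any of 6 WAA or replicate 2, 3 or 4 of 7 WAA (limma, adjusted p between 0.0683 and 0.211). VIT_204s0008g03920 also did not pass in a fit of all 26 libraries (limma, adjusted p = 0.139) or with whole units (0.0527). The count was 81 without replicate 1 of 7 WAA, 44 without replicate 2 of 7 WAA, 62 without replicate 1 of 6 WAA and 18 without replicate 2 of 6 WAA.

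The remaining lists passed no camera or fry test in any comparison. The lists for abscisic acid synthesis and breakdown (3 tested loci), sugar transport and invertase (4) and ripening switch regulators (7) held few loci, and 0 of their members passed over all loci. In development, 1 member of the abscisic acid list passed between 6 and 8 WAA and 1 of the ripening switch list between 6 and 7 WAA, both only when adjusted over the list alone. Within the proanthocyanidin list, 1 member passed the 1-MCP comparison at 8 WAA adjusted over the list alone. It was listed at 0 in 5 of 5 controls and at 1 unit in 3 of 5 treated clusters, and 0 members passed without the block for plants. Of the 8 loci of the anthocyanin list, 7 were listed at 0 in all 26 libraries, and the other one spans several identifiers, so the list was not tested. The 2 loci of the stilbene regulator list were too few to test. In several list tests that did not pass, the median, the mean and the direction given by camera differed in sign.

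Whether treated clusters lagged or led in development was examined along the change between control clusters of the other weeks, so that no library was shared. At 6 WAA the 1-MCP fold changes of 102 loci had a Pearson correlation of -0.11 across loci with the change from 7 to 8 WAA (Spearman -0.10), with a mean slope over plants of -0.0448 ± 0.0764 (SD, n = 3, exact sign-flip p = 0.50, smallest possible 0.25). Over all 17172 loci the correlation was -0.012 and the mean slope -0.0126 (exact p = 0.75). At 7 WAA the correlation over 205 loci with the change from 6 to 8 WAA was -0.088 (Spearman -0.016), and slopes were above 0 in 2 of 5 plants and below 0 in 3 (mean -0.0263 ± 0.2054, SD, n = 5, exact p = 0.8125). The correlation turned to 0.0651 without replicate 2 and to 0.0407 without replicate 3. At 8 WAA the correlation over all 17172 loci with the change from 6 to 7 WAA was 0.059 (Spearman 0.043), and slopes were above 0 in 5 of 5 plants (mean 0.0463 ± 0.0289, SD, n = 5). The exact p of 0.0625 was the smallest that 5 plants can give, and the adjusted p over the 3 weeks was 0.1875. Loci are not independent replicates, so the correlations across loci carry no p. On a scale where controls average 0 at 6 WAA and 1 at 8 WAA over those 205 loci, the clusters of 7 WAA lay at 0.40 ± 0.10 in controls and 0.41 ± 0.17 in treated clusters (SD, n = 5).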

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

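The counts of other splits and the tests of library totals, of the stilbene list against its technical explanations and of development in treated libraries were chosen only after the results were seen.

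Among 45 groups of 5 values checked for a value far from the others, 7 held one. Chance gives about 1 in 20 for continuous values, a rate that does not hold for the list totals, which are small whole numbers. Control replicate 3 of 8 WAA had 22 units over the flavonoid backbone list. Treated replicate 3 of 7 WAA had 21 units over the stilbene synthase list. In 4 of the 7 groups the value differed by 1 unit from the other 4, which were all equal, so it was not far from them. These were control replicate 2 (4 units) and treated replicate 1 (4 units) of 7 WAA and treated replicate 5 of 8 WAA (3 units) on the proanthocyanidin list, and control replicate 4 of 7 WAA (2 units) on the abscisic acid list. Treated replicate 1 of 8 WAA lay at 0.684 on the scale from 6 to 8 WAA, below the other 4 treated libraries of that week.

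The effect of 1-MCP differed at 7 loci between 6 and 7 WAA and at the same 7 loci between 6 and 8 WAA. Chance could not be excluded for either, since 48 of 100 and 36 of 100 exchanges of labels within plants gave as many, with up to 12 and 11 loci. For the average over weeks, 34 of 100 exchanges gave at least the 7 loci, with up to 12. Resampled data sets without change gave at most 6 loci between 6 and 7 WAA, 4 between 6 and 8 WAA and 6 on average. These lie below the real 7, but the resampling removed the links between libraries and between loci that the exchanges keep. At 6 WAA, 8 of 10 splits gave at least the real 8 loci and the highest other gave 244, but 10 splits are too few to bring a share under 0.05. Some splits that keep both clusters of a plant in one group called many times more loci. With the block for plants, such a plant adds nothing to the effect, so these splits rest on fewer plants. Their counts therefore cannot be compared with the real one and say nothing about a structure of the samples. Among the 4 splits that part all plants, 2 gave at least the real 8 loci, the real split included, and the highest other gave 8. At 7 WAA 87 of 100 splits gave at least the real 1 locus (up to 186). So did 6 of the 14 splits that part all plants (up to 10), so chance was not excluded. At 8 WAA and between 7 and 8 WAA limma called 0 loci, so there was no call to test, and any of the 100 splits gives at least 0. In limma, 841 and 899 loci had an unadjusted p under 0.05, both below a share of 0.05 of the tested loci. Other splits gave up to 137 loci at 8 WAA (3 among those that part all plants) and up to 3 between 7 and 8 WAA.

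In controls, chance was unlikely to give the calls from 7 to 8 WAA, where 1 of 100 splits, the real one, gave 102 loci and the highest other gave 11. The same holds from 6 to 8 WAA, where 1 of 56 splits gave 205 and the highest other gave 27. These shares are the smallest that the splits can give, and they were not adjusted over the comparisons. From 6 to 7 WAA, 3 of 56 splits gave at least the real 29 loci, up to 41, so chance was not excluded.

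The stilbene synthase list differed in its response between 6 and 7 WAA (camera adjusted p = 0.0330) and between 7 and 8 WAA (0.000189), but not with an estimated correlation (adjusted p = 0.978 and 0.403). The higher list total in treated clusters at 7 WAA is not explained by larger libraries, because the median ratio of list totals was 1.5 against 1.024 for library totals, and leaving out any 1 plant left a mean difference between 15.5 and 24.0 units. Neighbouring loci that move as one, near-identical copies among them, remain an open technical explanation of the strength of the call. The adjusted p of camera rose to 0.0876 once the correlation between loci was estimated. A response of stilbene synthesis to 1-MCP stays open as a hypothesis, and the list may hold loci of other genes.

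A scaling by the step drops out of the library totals by construction, since units are values divided by that step. In the 6 plants whose libraries share the step all 6 treated libraries held more units, but this adds no further test of scaling. The treated excess in library totals is not accounted for by more detected loci alone, since units per detected locus also rose by 0.0356. Sequencing depth, which is unknown here, was not tested and stays open. A wider range of transcripts in treated clusters also stays open. The number of detected loci, higher in 8 of 13 treated clusters, did not pass (exact sign-flip p = 0.229).

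Most loci called from 7 to 8 WAA in controls were lower at 8 WAA, when control libraries held fewer units. In the treated libraries, which were not used to find these 94 loci but come from the same plants, 91 were lower at 8 WAA and the median log2 change was -0.815. Treated libraries also held fewer units at 8 than at 7 WAA, with a log2 ratio of their mean totals of -0.067. Detected loci fell as well, from 14815.2 to 14144.4 on average in controls and from 14902.4 to 14399.2 in treated clusters. A locus that goes from 1 unit to 0 changes by about 1 on this log2 scale whatever the library total. The median of these loci therefore cannot tell smaller libraries from a loss of transcripts. Of these loci, 77 were detected in every control at 7 WAA and in no control at 8 WAA. Control replicate 3 of 8 WAA lacked them with 22076 units and 14542 detected loci. Control replicate 3 of 7 WAA held them with only 21368 units and 14496 detected loci. This argues against smaller libraries as the only cause for these 77, but it rests on that 1 library of 8 WAA. For the other loci smaller libraries stay open. For all 94 loci a loss of transcripts at the onset of ripening stays open as a hypothesis. So does a difference between the plants sampled in each week, if these were different plants, which was not tested.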

How the results depend on the processing

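Isoform-level values, sums per reference identifier, whole units, trend and robust moderation and all alternatives for library totals were chosen after seeing the data. The edgeR, DESeq2 and voom fits and the TMM and size-factor scalings intended for counts were not run because the values are not counts. Where none is named, the cause was not tested. Without the block for plants, 19 loci passed at 6 WAA and 5 at 8 WAA, and no other call count of 1-MCP moved by over 1.5 times. In fits with only the week or weeks compared, 140 loci passed at 6 WAA, 4 at 7 WAA (XLOC_011243 not among them), 4 at 8 WAA, 11 between 6 and 7 WAA and 26 between 6 and 8 WAA. With a filter at 5, which left 551 loci for 1-MCP and 339 for development, 1 locus passed at 8 WAA and 0 in every other 1-MCP comparison, and 0, 3 and 3 passed from 6 to 7, 7 to 8 and 6 to 8 WAA. A pseudocount of 0.1 gave 0 at 7 WAA and 4 at 8 WAA. A log2 fold change of at least 1 left 0 at 7 WAA, 0 for the average and 4 between 6 and 8 WAA. Rounding to whole units moved no count by over 1.5 times. When the loci with 1 value in all libraries were also left out, 0 loci passed at 7 WAA, on average and between 6 and 7 WAA and 1 between 6 and 8 WAA, while 6 passed at 6 WAA and 27, 118 and 223 in development from 6 to 7, 7 to 8 and 6 to 8 WAA. With only loci that differed from their median in at least 5 libraries, the counts were 0 at 6 WAA, 0 at 7 WAA, 0 on average, 0 between 6 and 7 WAA and 1 between 6 and 8 WAA, and 2, 123 and 110 in development. That filter removes changes seen only in 3 libraries of 6 WAA by construction, so its counts with 6 WAA say nothing about them. Isoform-level values gave 3 at 7 WAA, 47 from 6 to 7 WAA and 98 from 6 to 8 WAA. For 6 to 8 WAA no filter gave 105 and the replicate block across weeks, a pairing that the labels do not give, gave 103. With that block 1 count moved by over 1.5 times, and 11 of the 13 calls of named loci in development did not pass (limma, adjusted p 0.056 to 0.348), those of VIT_204s0044g00700 (0.123 from 6 to 8 WAA and 0.348 from 6 to 7 WAA) among them, while VIT_214s0030g00575 and VIT_203s0063g02050 did. Of the 6 list calls, 0 held with an estimated correlation, and fry made 2 other calls. Leaving out 1 plant or control, added after seeing the data, ended 3 of the 6 in camera and both fry calls at least once.

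Leaving out 1 plant gave 15 to 21 loci at 6 WAA, 0 to 2 at 7 WAA, 0 to 3 at 8 WAA, 4 to 18 on average, 8 to 22 between 6 and 7 WAA, 0 to 3 between 7 and 8 WAA and 7 to 23 between 6 and 8 WAA. Leaving out 1 control gave 18 to 81 from 6 to 7 WAA, 91 to 146 from 7 to 8 WAA and 96 to 141 from 6 to 8 WAA. On the ripening axis the correlation was -0.158 to -0.005 at 6 WAA, -0.247 to 0.0651 at 7 WAA (0.0651 without replicate 2, 0.0407 without replicate 3, and 0.0042 with all tested loci) and 0.0418 to 0.0606 at 8 WAA. The treated excess of units was 643.6 to 871.5 without any 1 plant and 626.8 in the deposited values, past the threshold each time. Among loci chosen for naming, 435 recomputed values kept their side of the threshold, 7 newly passed and none changed direction. Another 142 fell short of the threshold of the adjusted p or, in that alternative, of the fold change. The 435 include loci at 8 WAA and between 7 and 8 WAA that had not passed and again did not pass. With 64% to 70% of detected loci at 1 unit, the step of 1 unit limits what any of these fits can resolve.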

Other observations

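All tests in this part were chosen after the results were seen.

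Most changes to 8 WAA found in controls had the same direction in treated clusters. Of the 170 loci lower at 8 than at 6 WAA in controls, 148 were lower in treated clusters, against 37% of all tested loci, and of 35 higher loci, 30 were higher, against 34.4%. Of 8 loci higher at 8 than at 7 WAA, 6 were higher in treated clusters. From 6 to 7 WAA the carry-over was weaker, with 12 of 19 lower loci lower in treated clusters (34.6% of all loci, median log2 change -0.14 against -1.16 in controls) and 6 of 10 higher loci higher (36.7% of all loci, 0.27 against 1.37). The median log2 change was smaller in treated than in control clusters in each of these sets, which is expected in part because the loci were picked on the control values.

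Some loci with the smallest p at 8 WAA stood in treated clusters where 7 WAA controls stood, which led to the hypothesis that 1-MCP holds back the change from 7 to 8 WAA. It came from the same plants it was tested in. For each plant, the treated-minus-control difference was set against the change from 7 to 8 WAA in controls without that plant's own control, over the 91 to 132 loci past the threshold there. The slope was below 0 in 5 of 5 plants, with a mean of -0.1236 ± 0.0786 (SD, n = 5, exact sign-flip p = 0.0625, the smallest possible). Of the 4 loci named at 8 WAA, which prompted the question, 2 or 3 were among those loci, and without them the slope was below 0 in 4 of 5 plants (mean -0.0887 ± 0.0877, SD, n = 5, exact p = 0.125). Over all loci the slope was below 0 in 3 of 5 plants (mean -0.0171, exact p = 0.375), and along the change from 6 to 8 WAA it was below 0 in 3 of 5 (mean -0.0261, exact p = 0.5625; mean 0.0192 over all loci, exact p = 0.50). At 7 WAA the slope along the change from 6 to 7 WAA was above 0 in 4 of 5 plants (mean 0.0911, exact p = 0.375; mean 0.0069 over all loci, exact p = 0.9375). A partial delay may be present at 8 WAA, but part of the slope came from the loci that prompted the question, and 5 plants cannot bring this test under 0.05.

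The values are whole multiples of 1 step per library. The reading of a unit as 1 sampled read is argued against by the variance within groups, at most 0.348 times the mean where sampled reads would give at least 1. A candidate explanation is that a unit counts assembled transcript models per library, which was not tested. Of the loci, 1998 had the same whole value above 0 in all 26 libraries, and 2.94% of detected locus values exceeded the locus's number of isoforms.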
